A study of Mus musculus with 10 samples.

How the data were processed

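ATAC-seq libraries were made from Treg cells sorted from mixed bone marrow chimeras (mouse, spleen and lymph nodes), with 3 libraries each of WT cTreg and WT eTreg cells and 2 each of FntbKO cTreg and FntbKO eTreg cells. The deposited table holds raw read counts, without normalization, for 77076 regions common to the 10 libraries. Per the labels, the authors' processing used Trimmomatic 0.36, Picard 2.9.4, SAMtools, MACS2 2.1.1 and bedtools with the builds mm10 and GRCm38. The aligner and the way in which the regions were merged are not given in the labels used here. Between 66.73% and 79.24% of the counts in a library were even, as if the mates of a read pair had been counted separately, so the counts are not all independent and halved counts were tried as an alternative. Coordinates are printed as in the table, which does not state whether they start at 0 or 1. There were 2024 regions on the X chromosome, 0 on the Y chromosome and 53 on 10 scaffolds. The median width was 352 bp.

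Regions were assigned to protein-coding genes with a table of gene spans of GRCm38.p6. A region took the gene whose span it overlapped, or otherwise the nearest span within 100 kb. This departs from the plan, which named the nearest transcription start site, because the gene table gives neither strand nor exons. For the same reason distances were measured to either gene end. Of all regions 72671 (94.3%) received a gene, 48433 (62.8%) lay inside a span, and 15450 genes had at least 1 region. An assigned gene is a position, not a shown target of the region. No genome sequence was at hand, so motif enrichment and corrections for GC content and width were not run.

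Counts were scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), with robust dispersions, filterByExpr on the 4 groups and a design of 1 mean per group, which leaves 6 residual degrees of freedom. All 10 libraries entered the fit. The FntbKO groups hold 2 libraries each, so all groups share their estimate of the spread. The comparisons were eTreg against cTreg in WT and in FntbKO, FntbKO against WT in cTreg and in eTreg, and the interaction of genotype and subset. A region was called at a Benjamini-Hochberg adjusted p under 0.05 over 76216 tested regions. Log2 fold changes are given with the SE of the fit. CPM values are TMM-scaled, with SD over the libraries of a group. No fold is given where a group had at most 3 counts in all. The SE takes in the spread between libraries, while the intervals and bounds below are over regions and do not measure that spread.

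Before the data were examined, the comparisons, 14 pathway lists, 6 lists of cell type markers, the alternatives and the rule for naming regions were fixed. The rule takes, among called regions with a mean log2-CPM at or above the median of tested regions (2.42) and with compared groups that do not overlap, the largest change per named gene, and names the 10 highest rises and the 10 largest falls. It adds all regions of Fntb and Foxp3, and up to 4 called members of each list, or up to 2 with the smallest p where none is called. The Slc39a11 interval and the other runs of neighbouring calls are outside this rule.

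Lists were tested with camera of limma 3.58.1 on voom values, with an inter-gene correlation of 0.01, over the regions of the list's genes against all other tested regions, with adjustment over the 20 lists of a comparison. Each test was repeated with a correlation estimated from the residuals, and no list passed in any comparison with it. Results for 1 of the lists and for 1 list gene are not reported here. Called regions of a list were also counted with p-values adjusted over the list alone, and their share was compared with that of other regions by Fisher's exact test. Library measures were compared by two-sided exact permutation tests over 210 or 252 arrangements, and positions by two-sided Fisher's exact tests.

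The call rate was tested on simulated data made from these counts with known changes. Recovery at 2-fold and 4-fold was 38% and 82% for the subset comparison in WT, 34% and 72% in FntbKO, 36% and 74% for the genotypes in cTreg, 44% and 74% in eTreg, and 22% and 48% for the interaction. Between 2 and 6 calls per comparison were false, of 59 to 114 calls in all. In each simulation 50 regions were changed at each fold, in a single group. Recovery may differ where more regions change. The simulated counts were independent, with a dispersion that follows the mean count, and held no region-specific spread, separately counted mates or outlying libraries. Recovery and false calls in the real data may therefore differ. Pairs of libraries within a group differed by more than counting error, with a chi-square per region of 2.48 to 3.69. Mates counted separately raise this value by themselves, so the excess over counting error may be smaller than it seems.

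The alternatives were DESeq2 size factors and total counts as scaling, cyclic loess with limma, no filter and a filter at 5 CPM in at least 2 libraries, DESeq2 1.42.0, limma-voom, fits of the compared groups alone, replicate numbers as blocks, a stricter threshold, a minimum change of 1.5-fold, leaving out the X chromosome and leaving out each library in turn. For the lists they were genes within 10 kb and 1 value per gene. Halved counts, leaving out WT cTreg 2 and FntbKO cTreg 1 together, and leaving out clustered regions were added after the data were seen. Residuals of libraries that share a number correlated at 0.165, 0.083 and 0.032 between the subsets of WT and 0.18 between those of FntbKO, and from -0.078 to 0.141 between the genotypes. Between the subsets, libraries of different number correlated from -0.13 to 0.044 in WT and at -0.18 in FntbKO. With 2 libraries per group, the FntbKO value mirrors that of the same number by construction. The labels do not say that a number marks an animal and these values do not settle it, so the replicate block was kept as an alternative only. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.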

Results

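Chromatin accessibility was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in regulatory T (Treg) cells sorted from the spleen and lymph nodes of mixed bone marrow chimeras, animals whose blood cells derive from marrow of different donors. The cells were central Treg (cTreg) or effector Treg (eTreg) cells and were wild type (WT) or deficient in Fntb (FntbKO). Fntb encodes the β subunit of protein farnesyltransferase, the enzyme that attaches a farnesyl lipid to proteins such as RAS and the nuclear lamins. There were 3 libraries of WT cTreg, 3 of WT eTreg, 2 of FntbKO cTreg and 2 of FntbKO eTreg cells. Read counts were given for 77076 regions. The total counts were 7259480, 5694869 and 9347634 in the WT cTreg libraries and 8427620, 9822626 and 5946131 in the WT eTreg libraries. They were 7450914 and 15328775 in the FntbKO cTreg libraries and 5058328 and 10126587 in the FntbKO eTreg libraries.

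The first principal component held 32.6% of the variance. It placed the WT eTreg libraries between 65 and 130.2, the FntbKO eTreg libraries at 0.7 and 28.7, the WT cTreg libraries between -56.7 and 9, and the FntbKO cTreg libraries at -155.3 and -67.1. WT cTreg 2 lay nearest to the eTreg libraries among the cTreg libraries, and FntbKO cTreg 1 lay farthest from them. Total counts, the percent of counts on the X chromosome, near gene ends and in the most covered regions were compared between genotypes and between subsets in 8 two-sided exact permutation tests. The smallest adjusted p was 0.825. The p-values of single regions and of these permutation tests measure only the spread between these samples. The set tests of gene lists and Fisher's exact tests below compare regions with other regions, so their p-values do not measure replication across samples.

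The Fntb locus itself differed between the genotypes in both subsets. Fntb (gene 110606) spans 76837400 to 76921412 on chromosome 12 of GRCm38. The region at the start of this span (76837192 to 76837915) had 33.1 ± 3.81 CPM (SD, n = 3) in WT cTreg and 12.1 ± 1.4 (n = 2) in FntbKO cTreg cells. It had 30.0 ± 0.492 (n = 3) in WT eTreg and 9.55 ± 2.93 (n = 2) in FntbKO eTreg cells. The log2 fold change of FntbKO over WT was -1.46 (SE 0.18, edgeR adjusted p = 6.34e-05) in cTreg and -1.71 (SE 0.19, adjusted p = 4.46e-05) in eTreg cells, and both calls remained when any single library was left out. A second region of the Fntb span (76844676 to 76845058) was lower by a log2 fold of -2.10 (SE 0.33, adjusted p = 0.00154) in cTreg, a call lost without FntbKO cTreg 1. In eTreg cells it had a log2 fold of -1.69 (SE 0.38, adjusted p = 0.0448), lost without any of 6 libraries. Another Fntb region (76874004 to 76874477) was higher in FntbKO eTreg cells, with a log2 fold of 0.90 (SE 0.20, adjusted p = 0.0413), a call also lost without any of 6 libraries. The remaining Fntb regions among the 13 tested were not called in either subset. Which part of Fntb was deleted is not given in the labels, so these regions do not map the deletion. None of the 3 tested regions of Foxp3, the transcription factor that defines Treg cells, was called in any comparison.

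**Figure D1:**
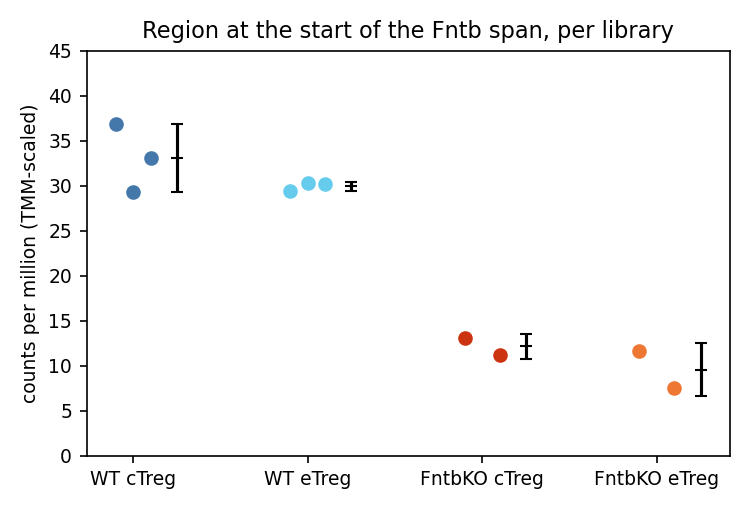
Library-scaled counts (CPM, vertical axis) of the region at the start of the Fntb span in each of the 10 libraries by group; points are libraries, and the dash with bars beside them is the mean with its SD. The FntbKO means of 12.1 (cTreg) and 9.55 (eTreg) lie below the WT means of 33.1 and 30.0.

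The comparison of WT eTreg with WT cTreg cells asks which chromatin opens or closes between the subsets when Fntb is present. Some regions beside central Treg genes closed in eTreg cells, and some regions beside effector genes opened. A region beside Ccr7, the receptor that guides T cells into lymph nodes, fell by 0.82 on the log2 scale (SE 0.14, adjusted p = 0.00201; chromosome 11, 99170670 to 99171340). A region of the transcription factor gene Bach2 fell by 1.27 (SE 0.27, adjusted p = 0.0106; chromosome 4, 32393228 to 32393608), a call lost without WT cTreg 3 or WT eTreg 3. In the other direction, a region beside Klrg1, an inhibitory receptor of effector lymphocytes, rose from 3.46 ± 1.43 to 13.7 ± 2.35 CPM (SD, n = 3 each), a log2 fold of 1.96 (SE 0.34, adjusted p = 0.00256; chromosome 6, 122262538 to 122263143).

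Of 76216 regions tested with edgeR, 2619 were called at an adjusted p of 0.05, with 1393 higher and 1226 lower in eTreg. The median log2 fold was 1.26 and -0.93 in these directions. It was 1.21 and -0.92 without the 76 and 6 regions in which a compared group had at most 3 counts in all. The strongest rises by the rule for naming regions included Serpina3f (1.84, SE 0.21, adjusted p = 0.000194), Vcpkmt (2.15, SE 0.29, adjusted p = 0.000578) and the tyrosine phosphatase Ptpn3 (1.87, SE 0.28, adjusted p = 0.000772). The strongest falls included Cdkal1 (-1.96, SE 0.35, adjusted p = 0.00256), Cyria (-1.83, SE 0.32, adjusted p = 0.00404) and Baz2b (-1.78, SE 0.29, adjusted p = 0.00172). By construction of this rule, the libraries of the compared groups did not overlap in any region named by its rank. Of the 82 named regions called here, 24 kept the call when each library was left out in turn, those of Ccr7, Klrg1, Serpina3f, Vcpkmt, Ptpn3, Cdkal1, Cyria and Baz2b among them. The count of called regions was 774 without WT cTreg 1, 818 without WT eTreg 1, 427 without WT cTreg 3 and 545 without WT eTreg 3. It was 4225 without WT cTreg 2 and FntbKO cTreg 1 together.

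Of 34 measured effector Treg genes, 15 had regions that rose, 2 had regions that fell, 2 had both and 15 had none called. Called regions of this list numbered 23 higher and 4 lower over all regions, and 38 higher and 14 lower adjusted over the list alone. The list lay above all other regions (median log2 fold 0.14, camera adjusted p = 0.00713; adjusted p = 0.281 with an estimated correlation). The region beside Tigit, an inhibitory receptor, rose by a log2 fold of 1.56 (SE 0.32, adjusted p = 0.00812), lost without WT cTreg 1, WT cTreg 3 or WT eTreg 3. Of 19 measured central Treg genes, 11 had regions that fell, 1 had both directions and 7 had none called. The list had 2 regions called higher and 44 lower, or 7 and 85 adjusted over the list alone, and lay below other regions (median -0.37, camera adjusted p = 1.12e-10; adjusted p = 0.281 with an estimated correlation). A region 62.7 kb from S1pr1, the receptor for exit from lymph nodes, fell by 3.68 (SE 0.82, adjusted p = 0.0133), lost without WT cTreg 3 or WT eTreg 3. It had 52 counts in all in WT cTreg and only 4 in WT eTreg cells, so the size of this fold is not exact. S1pr1 was the gene with both directions, with 2 regions called higher and 3 lower. Markers of conventional naive CD4 T cells moved with the central list, with which they share Ccr7, Lef1, Il7r and Dapl1 among others. They had 1 region called higher and 14 lower, 2 and 23 adjusted over the list alone (median -0.31, camera adjusted p = 6.55e-06; adjusted p = 0.281 with an estimated correlation).

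Among Treg identity genes, a region beside Ikzf2, which encodes Helios, rose by a log2 fold of 1.90 (SE 0.33, adjusted p = 0.00236) and a region of the surface receptor Nrp1 fell by 0.87 (SE 0.13, adjusted p = 0.000752). The list had 7 regions called higher and 4 lower, 8 and 4 adjusted over the list alone, and the set test gave an adjusted p of 0.379. Helper T cell subset genes had 14 regions called higher and 6 lower, 19 and 13 adjusted over the list alone, more than other regions did (Fisher's exact test, adjusted p = 4.91e-05). A region beside the cytokine gene Il17a rose by 1.74 (SE 0.24, adjusted p = 0.000749). The set test of this list did not pass (adjusted p = 0.85), and its median of -0.00155 differed in sign from the test's upward direction. The mTORC1 list had 8 regions called higher and 0 lower, the same numbers adjusted over the list alone, with an adjusted p of 0.175. A region of Asns, asparagine synthetase, rose by 1.10 (SE 0.21, adjusted p = 0.0038). AP-1, BATF and IRF family genes had 5 regions called higher and 12 lower, 8 and 16 adjusted over the list alone, with a set test adjusted p of 0.379, while the share of called regions was above that of other regions (Fisher's exact test, adjusted p = 0.0476). Of the 12 lower regions, 9 were assigned to Bach2, which is also in the central list. A region beside the transcription factor Maf rose by 1.37 (SE 0.20, adjusted p = 0.000772).

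For the other lists in WT cells, the set test gave adjusted p values as follows. It gave 0.774 for TCR-induced genes, with 11 regions called higher and 5 lower (12 and 5 adjusted over the list alone), and 0.153 for TCR signalling components, with 5 higher and 9 lower (5 and 11 adjusted over the list alone). Sterol synthesis genes had an adjusted p of 0.34, with 3 regions called higher and 0 lower, also adjusted over the list alone. The prenylation machinery had an adjusted p of 0.882, with 3 higher and 4 lower (6 and 4 adjusted over the list alone), more than other regions had (Fisher's exact test, adjusted p = 0.0292), and the 4 lower regions were all in Fntb. Interferon response genes had an adjusted p of 0.476 with no region called, and cell cycle genes 0.918 with 2 called higher, both unchanged when adjusted over the list alone. Apoptosis genes had an adjusted p of 0.175, with 1 higher and 6 lower (4 and 8 adjusted over the list alone). Markers of B, CD8 T or NK, myeloid, dendritic and erythroid cells did not pass the set test, but the myeloid list had the highest share of called regions of any list, 15.8% (Fisher's exact test, adjusted p = 0.00703). The set test adjusted p was 0.85 for B cells (1 region called higher, also adjusted over the list alone) and 0.774 for CD8 T or NK cells (1 higher and 3 lower, 1 and 7 adjusted over the list alone). It was 0.0858 for myeloid cells (5 higher and 1 lower, 6 and 2 adjusted over the list alone), 0.0858 for dendritic cells (1 higher and 2 lower, 4 and 2 adjusted over the list alone) and 0.175 for erythroid cells (1 lower, also adjusted over the list alone).

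The comparison of FntbKO eTreg with FntbKO cTreg cells asks for the same subset change in the absence of Fntb. Among effector genes, 8 of 34 had regions that opened, and among central genes 6 of 19 had regions that only closed. The region beside Il17a rose from 3.51 ± 0.715 to 14.9 ± 4.4 CPM (SD, n = 2 each), a log2 fold of 2.01 (SE 0.32, adjusted p = 0.00419), lost without FntbKO cTreg 1. A region beside Il1rl1, which encodes the IL-33 receptor, rose by 2.13 (SE 0.40, adjusted p = 0.0158) and a region beside the chemokine receptor gene Cxcr3 rose by 1.60 (SE 0.29, adjusted p = 0.00839). A region of the kinase gene Camk2a fell by 1.94 (SE 0.25, adjusted p = 0.000532; chromosome 18, 60952253 to 60952935).

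In FntbKO cells 1033 regions were called, with 736 higher and 297 lower in eTreg. Other strong rises were Gpr160 (2.22, SE 0.36, adjusted p = 0.00414) and Coro2a (2.14, SE 0.35, adjusted p = 0.00414), and another strong fall was Tshz1 (-1.89, SE 0.35, adjusted p = 0.00841). This comparison rested on few libraries. Of its 52 named called regions, only that of Camk2a kept the call without each library in turn. Of the 52, 1 remained without FntbKO cTreg 1, 2 without FntbKO eTreg 2 and 14 without FntbKO eTreg 1. The count of called regions was 5 without FntbKO cTreg 1, 10 without FntbKO eTreg 2, 191 without FntbKO eTreg 1 and 623 without WT cTreg 3. It was 2249 without FntbKO cTreg 2 and 1807 without WT cTreg 2. Without WT cTreg 2 and FntbKO cTreg 1 together it was 38.

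Effector Treg genes had 16 regions called higher and 0 lower, 29 and 0 adjusted over the list alone, in 8 of 34 genes (median 0.17, camera adjusted p = 0.000425; adjusted p = 0.417 with an estimated correlation). Central Treg genes had 2 higher and 8 lower, 2 and 9 adjusted over the list alone; 6 of 19 genes had falls and 2 had both directions (median -0.25, camera adjusted p = 3.67e-05; adjusted p = 0.417 with an estimated correlation). Naive CD4 markers had 1 higher and 3 lower, 1 and 4 adjusted over the list alone (median -0.22, camera adjusted p = 0.00027; adjusted p = 0.417 with an estimated correlation). Myeloid markers lay higher in FntbKO eTreg cells (median 0.23, camera adjusted p = 0.0179; adjusted p = 0.417 with an estimated correlation), with 1 region called higher, in Cebpb, and 6 higher adjusted over the list alone. Helper T cell subset genes had 10 regions called higher and 0 lower, 18 and 5 adjusted over the list alone (Fisher's exact test, adjusted p = 0.00202), while their median of -0.02 differed in sign from the upward set test (adjusted p = 0.437). The region of Lmnb1, which encodes the farnesylated lamin B1, rose by 1.26 (SE 0.26, adjusted p = 0.0172), and it also rose in WT cells (adjusted p = 0.00936). It lost the first call without FntbKO cTreg 1 or FntbKO eTreg 2 and the second without WT eTreg 1, WT cTreg 3 or WT eTreg 3. The other 15 lists had set test adjusted p values of 0.354 or more.

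Placed side by side, the subset change ran the same way in both genotypes. At regions called higher in WT eTreg cells the median log2 fold was 1.26 in WT and 0.92 in FntbKO, and 95.8% had the same sign in FntbKO. At regions called lower it was -0.93 and -0.54, and 94.9% had the same sign. Choosing regions in WT inflates the WT fold, and the mirror shows the same effect. At regions called higher in FntbKO the median was 1.30 in FntbKO and 0.66 in WT, and at those called lower -1.07 and -0.68. Of the called regions, 268 rose and 133 fell in both genotypes, against 13.5 and 4.78 expected for independent calls, and 0 were called in opposite directions. Across all tested regions, which are not independent replicates, the folds had a Pearson r of 0.506 and a Spearman correlation of 0.498. The FntbKO median at WT-higher regions was 0.70 without FntbKO cTreg 1 and 1.37 without FntbKO cTreg 2.

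**Figure D2:**
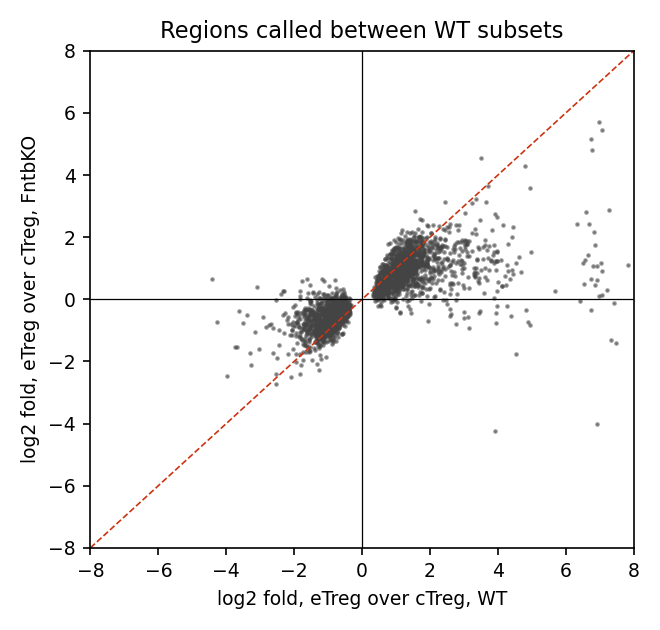
Log2 fold change of eTreg over cTreg cells in WT (horizontal axis) and in FntbKO (vertical axis) at the 2619 regions called in WT; each point is a region and the dashed line marks equal folds. Of the points right of 0, 95.8% lie above 0, and the points at the far right are regions with few or no counts in WT cTreg cells, whose fitted folds are not exact.

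The difference between these subset changes was tested directly as an interaction of genotype and subset. No region passed in edgeR, with 3099 regions at an unadjusted p under 0.05. DESeq2 and limma-voom also called 0, with 2133 and 3286 regions at an unadjusted p under 0.05. No list passed either, the lowest camera adjusted p being 0.253, shared by central Treg genes (median 0.10) and interferon response genes (median -0.10). On simulated changes of 4-fold this test recovered 48% of regions, and at 2-fold 22%. Differences of this size could thus often be missed at this depth and number of libraries.

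The comparison of FntbKO with WT cTreg cells asks what the loss of Fntb changes in the central subset. The largest changes among the named regions were falls. A region of Trim12a, a gene of the TRIM5 family, fell from 15.6 ± 1.03 (SD, n = 3) to 2.24 ± 1.23 CPM (n = 2), a log2 fold of -2.68 (SE 0.29, adjusted p = 2.61e-05; chromosome 7, 104314661 to 104315361). A region beside the neighbouring Trim5 fell by 2.73 (SE 0.32, adjusted p = 0.000167) and a region of Ptprm, a receptor-type phosphatase, fell by 2.88 (SE 0.35, adjusted p = 8.3e-05; chromosome 17, 67193881 to 67194472). A region beside Slc39a11, a zinc transporter gene, fell by 2.26 (SE 0.31, adjusted p = 0.000409; chromosome 11, 113196209 to 113196559). A region of Churc1, on chromosome 12 beside Fntb (76778486 to 76779123), fell by 2.08 (SE 0.30, adjusted p = 0.000486). Regions that rose included those of the thyroid hormone receptor gene Thrb (1.85, SE 0.26, adjusted p = 0.000486) and of the inflammatory caspase gene Casp4 (1.53, SE 0.29, adjusted p = 0.00845), and a region beside Fggy (1.54, SE 0.21, adjusted p = 0.000486).

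In cTreg cells 433 regions were called, with 145 higher and 288 lower in FntbKO. Cyclic loess scaling gave 110 higher and 371 lower, and limma-voom 221 higher and 204 lower, so the balance of directions depended on the method. Of 32 named called regions, 8 kept the call without each library in turn: the first Fntb region and those of Trim12a, Trim5, Ptprm, Slc39a11, Churc1, Chrne and Fggy. Without FntbKO cTreg 1 the calls of Thrb and Casp4 were lost, and that of Casp4 also without WT cTreg 3. The count of called regions was 41 without FntbKO cTreg 1, 201 without WT cTreg 2 and 723 without FntbKO cTreg 2, and 43 without FntbKO cTreg 1 and WT cTreg 2 together.

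Some regions beside genes of the effector and Treg identity lists were called in cTreg cells. A region of Lrrc32, whose product GARP holds latent TGF-β on Treg cells, fell by 0.92 (SE 0.17, adjusted p = 0.00861), and a region beside Maf fell by 1.22 (SE 0.22, adjusted p = 0.00566). A region of Nt5e, which encodes the ectoenzyme CD73, fell by 1.28 (SE 0.26, adjusted p = 0.0176), while a region beside Prdm1, which encodes Blimp-1, rose by 1.65 (SE 0.36, adjusted p = 0.0258). All of these calls were lost without FntbKO cTreg 1. That of Nt5e was also lost without WT cTreg 1, and that of Prdm1 without WT cTreg 1, WT cTreg 3 or FntbKO cTreg 2. A region beside Ctla4 had a log2 fold of -1.87 (SE 0.44, adjusted p = 0.0442), a call lost without any of 9 libraries. The effector list, with 1 region called higher and 4 lower in 5 of 34 genes (1 and 9 adjusted over the list alone), lay below other regions (median -0.12, camera adjusted p = 0.0285; adjusted p = 0.426 with an estimated correlation). Its share of called regions did not differ from that of other regions (Fisher's exact test, adjusted p = 0.788). Treg identity genes had 0 regions called higher and 2 lower, and their set test did not pass (camera adjusted p = 0.713). Central Treg genes lay higher with no region called, nor adjusted over the list alone (median 0.11, camera adjusted p = 0.0254; adjusted p = 0.492 with an estimated correlation). Naive CD4 markers did as well, again with none called on either scale (median 0.10, camera adjusted p = 0.0254; adjusted p = 0.492 with an estimated correlation). Interferon response genes lay higher (median 0.23, camera adjusted p = 0.00259; adjusted p = 0.132 with an estimated correlation), with 0 of 39 regions called over all regions and 3 higher adjusted over the list alone.

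Markers of other cells moved with the genotype in cTreg cells. B cell markers lay lower in FntbKO (median -0.45, camera adjusted p = 0.0116; adjusted p = 0.28 with an estimated correlation), and so did myeloid markers (median -0.24, camera adjusted p = 0.0254; adjusted p = 0.426 with an estimated correlation). Neither list had a region called over all regions, and adjusted over the list alone 2 and 3 fell. Without FntbKO cTreg 1, only 1 of the 6 lists of this comparison passed, and without WT cTreg 2 only 2 did. Without both of these libraries 1 list passed. The other 14 lists had set test adjusted p values of 0.0767 or more. The median and the test differed in sign for the prenylation machinery (0.03, downward), cell cycle genes (-0.00314, upward) and erythroid markers (-0.11, upward).

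The comparison of FntbKO with WT eTreg cells asks what the loss of Fntb changes in the effector subset. The Trim12a region was again lower, at 2.58 ± 0.81 (SD, n = 2) against 16.5 ± 2.93 CPM (n = 3), a log2 fold of -2.59 (SE 0.31, adjusted p = 8.49e-05), as was that of Ptprm (-2.40, SE 0.39, adjusted p = 0.0037). The Klrg1 region had 3.57 ± 0.517 CPM (n = 2) in FntbKO eTreg cells against 13.7 ± 2.35 (n = 3) in WT, a log2 fold of -1.90 (SE 0.39, adjusted p = 0.0275). The Ccr7 region was higher in FntbKO by 0.93 (SE 0.15, adjusted p = 0.00495). These regions were also called between the WT subsets, a comparison that uses the same WT eTreg libraries, and in the interaction test neither Klrg1 (log2 -1.30, edgeR adjusted p = 1) nor Ccr7 (log2 0.85, edgeR adjusted p = 1) passed. A region beside Tfrc, the transferrin receptor gene, rose by 1.47 (SE 0.33, adjusted p = 0.0387), and a region of Ly75, which encodes the receptor DEC-205, rose by 1.39 (SE 0.18, adjusted p = 0.000755; chromosome 2, 60370092 to 60370702). A region beside the proliferation marker Mki67 fell by 0.73 (SE 0.14, adjusted p = 0.0203), and by 0.84 in cTreg cells (SE 0.14, adjusted p = 0.00349).

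In eTreg cells 267 regions were called, with 138 higher and 129 lower in FntbKO. Cyclic loess scaling gave 143 higher and 183 lower, and limma-voom 166 higher and 89 lower, so the balance depended on the method here too. Of 26 named called regions, those of Trim12a and the start of Fntb kept the call without each library in turn. The Klrg1 call was lost without any of the 5 eTreg libraries, that of Ccr7 without WT eTreg 3 or FntbKO eTreg 2, and that of Ly75 without FntbKO eTreg 2. The Ptprm call was lost without either FntbKO eTreg library, that of Mki67 also without WT eTreg 3, and that of Tfrc without any of 5 libraries. In cTreg cells the Mki67 call was lost without FntbKO cTreg 1. Of the 26, 4 remained without FntbKO eTreg 2, 5 without FntbKO eTreg 1 and 7 without WT eTreg 3. The count of called regions was 9 without FntbKO eTreg 2, 33 without FntbKO eTreg 1, 39 without WT eTreg 3, 73 without WT eTreg 1 and 152 without WT cTreg 3. It was 507 without WT cTreg 2 and 698 without WT cTreg 2 and FntbKO cTreg 1 together.

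Central Treg genes lay higher in FntbKO eTreg cells, with 2 regions called higher, both beside Ccr7, and 1 lower, in the complement regulator Cd55 (6 and 2 adjusted over the list alone; median 0.23, camera adjusted p = 0.000133; adjusted p = 0.377 with an estimated correlation). Naive CD4 markers lay higher as well, with the same 2 regions called and 3 adjusted over the list alone (median 0.17, camera adjusted p = 0.0127; adjusted p = 0.392 with an estimated correlation). AP-1, BATF and IRF family genes lay higher (median 0.15, camera adjusted p = 0.0306; adjusted p = 0.118 with an estimated correlation), with 0 regions called higher and 1 lower, beside the stress response factor Nfe2l2, and 3 and 2 adjusted over the list alone. Only 1 of these 3 lists passed without WT eTreg 1, WT eTreg 3 or FntbKO eTreg 1. The effector list had 1 region called lower, that of Klrg1, also adjusted over the list alone, and an adjusted p of 0.264. The prenylation machinery had more called regions than others (1 higher and 2 lower, Fisher's exact test adjusted p = 0.036), all of them in Fntb. Markers of cells outside the T lineage did not pass the set test, but myeloid markers had 0 regions higher and 5 of 38 lower adjusted over the list alone (median -0.07, camera adjusted p = 0.188), and B cell markers had a median of -0.31 (camera adjusted p = 0.188) with no region called on either scale. The 17 lists that did not pass had set test adjusted p values of 0.133 or more.

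The genotype difference was partly shared by the subsets, which have no library in common. In both subsets 27 regions were called higher and 69 lower in FntbKO, against 0.263 and 0.487 expected for independent calls. None had opposite directions. The labels do not say whether both subsets came from the same animals or donors, and all groups share their estimate of the spread. The 2 comparisons may therefore not be independent. The shared falls included Trim12a, Trim5, Ptprm, Churc1, Slco3a1 and the start of Fntb. Across regions, which are not independent replicates, the folds had a Pearson r of 0.376 and a Spearman correlation of 0.379. The count of shared regions, 96 in all, was 7 without FntbKO eTreg 2, 16 without FntbKO eTreg 1, 25 without WT eTreg 3, 33 without FntbKO cTreg 1, 37 without WT eTreg 1 and 56 without WT cTreg 3.

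The shared falls included a run of neighbouring regions beside Slc39a11, singled out after its values were seen. Between 113060975 and 113268225 on chromosome 11, a stretch of 207.2 kb, all 23 tested regions were lower in FntbKO in both subsets, and 15 were called in cTreg and 10 in eTreg cells. Their weighted mean log2 fold was -1.47 in cTreg and -1.20 in eTreg cells. Other windows of 1 Mb with several calls held Trim5, Trim12a and Trim30d on chromosome 7, where 5 of 23 tested regions fell in each subset, and Cfap20dc on chromosome 14, where 5 of 31 fell in cTreg cells.

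**Figure D3:**
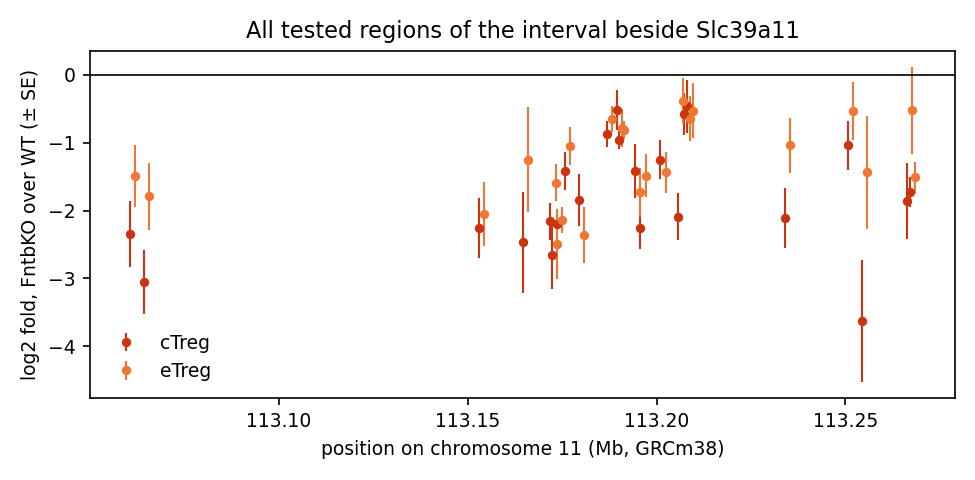
Log2 fold change of FntbKO over WT with its SE (vertical axis) at each of the 23 tested regions of the interval beside Slc39a11, by position on chromosome 11 in Mb (horizontal axis), for cTreg and eTreg cells, drawn slightly apart sideways. All points lie below 0, the highest in cTreg cells at -0.47 and the lowest at -3.63.

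The regions that differed between the subsets lay away from gene ends. Of all tested regions, 18.0% lay within 1 kb of an annotated gene end. Among regions called in WT this was 7.5% of those higher in eTreg (odds ratio 0.363, Fisher's exact test, adjusted p = 1.9e-29) and 5.0% of those lower (0.235, adjusted p = 1.04e-41). In FntbKO it was 6.5% (0.315, adjusted p = 2.75e-19) and 6.4% (0.31, adjusted p = 1.73e-08). Regions called between the genotypes were also less often near gene ends in cTreg cells, with 11% of the higher (0.564, adjusted p = 0.0341) and 12.5% of the lower (0.65, adjusted p = 0.0184). In eTreg cells 2.2% of the higher (0.101, adjusted p = 1.73e-08) and 14.0% of the lower regions (0.738, adjusted p = 0.253) lay there, and the last did not pass. Neighbouring regions are not independent, so these p-values are only approximate.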

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

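The test for regions that lie close together, the tests of the flank of Fntb and of a shared dosage at Slc39a11, the test of depth and the second form of the test for admixed cells were chosen only after the result was seen.

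In 4 regions every eTreg library lay on 1 side of every cTreg library in WT and on the opposite side in FntbKO. Near Cd69 (chromosome 6, 129228996 to 129229499) the interaction was a log2 fold of 0.69, from -0.47 in WT and 0.22 in FntbKO, with an unadjusted p of 0.00527. In Mvd (chromosome 8, 122436201 to 122436447) it was -0.96, from 0.51 and -0.45, with an unadjusted p of 0.0278. In Ccnd3 (chromosome 17, 47511068 to 47511509) it was 0.54, from -0.19 and 0.34, with an unadjusted p of 0.00946. In Lef1 (chromosome 3, 131169203 to 131169687) it was 0.92, from -0.36 and 0.56, with an unadjusted p of 0.00418. The adjusted edgeR p of the interaction was 1 in all 4. With no subset difference in any region, chance gives such opposite separation in 1.67% of regions, or 4.1 of the 245 named regions checked. Some of these had been named for a low interaction p, which raises the number expected. Many others had been named for a subset difference, which lowers it, so 4.1 is only a rough guide. No explanation was tested for these 4.

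Between the WT subsets 2619 regions were called, and the most in any other split of the 6 WT libraries was 2. The real split was 1 of 10 with as large a count, which is too few splits for a share under 0.05. Every other split has both subsets on each side, so the subset difference widens the spread within its groups and lowers its calls. The count of 2 is therefore no measure of the calls that chance gives.

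The FntbKO eTreg libraries scored lower than held-out WT eTreg libraries on an axis from cTreg to eTreg, built from 500 regions per direction in the other WT libraries, by -0.84 (SD 0.27 over 3 hold-outs), and the mean of the FntbKO cTreg libraries was lower than WT cTreg by -0.30, -1.26 (against WT cTreg 2) and -0.33, though FntbKO cTreg 2 alone scored above WT in 2 of 3. Lower depth argues poorly for this, since the deeper FntbKO eTreg library scored -0.68 (SD 0.32) relative to WT. If cTreg cells had been sorted with the FntbKO eTreg cells, the opening and closing regions should give equal shares of them. The closing regions gave a share lower by -6.6 percentage points (SD 2.9), and by -6.3 (SD 2.4) with FntbKO cTreg cells as the admixed type, but these differences are small beside the shares (57% and 50.7% for FntbKO eTreg 1 in the first hold-out), the 6 values come from 2 libraries, and a part of the shift may still be such cells. In the genotype comparison in eTreg cells the central list lay higher (camera adjusted p = 0.000133; adjusted p = 0.377 with an estimated correlation) and the effector list did not pass (camera adjusted p = 0.264), and a biological difference in either subset stays open.

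The regions called between genotypes in cTreg cells lay closer together than others, with 30.5% (95% interval 26.2 to 35.1, exact binomial) within 100 kb of another call in the same direction. For as many lowest-p regions this was 18.9% (15.4 to 23.0) in the FntbKO subset comparison, 9.9% (7.3 to 13.1) in the WT subset comparison and 8.1% in random draws. All these intervals take regions as independent, although neighbouring calls count for each other, so they are too narrow. That the cTreg interval does not overlap the others is therefore not firm. Differences in DNA between the donors of FntbKO and WT cells may contribute, and in eTreg cells this stays open: the 433 lowest-p regions gave 21.9% (18.1 to 26.1) and the 267 called regions 17.2% (12.9 to 22.3), against 18.9% and 19.1% for as many in the FntbKO subset comparison. A segment of other origin around Fntb is argued against by an odds ratio of 0.772 for calls within 10 Mb of it, leaving out 200 kb centred on Fntb with the calls of Fntb itself. Its upper bound of 1.999 lies barely under the limit of 2 that was set after the data were seen, so it is weak evidence, and a shorter segment and coordinated regulation of neighbouring regions stay open.

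At the Slc39a11 interval all 23 regions were lower in FntbKO in both subsets. A loss of copies across the whole interval predicts folds that scatter around 1 value, and by the test fixed first, 0 regions lay over 3 SE above the weighted mean in both subsets, as a loss would give. A test of heterogeneity chosen afterwards argues against 1 shared dosage, with a Cochran Q of 123 in cTreg and 85 in eTreg cells on 22 degrees of freedom, taking the regions as independent. A smaller or more complex change of DNA, and regulation of the interval, could each remain.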

How the results depend on the processing

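Halved counts, the joint omission of WT cTreg 2 and FntbKO cTreg 1, the removal of clustered regions and the omission of libraries from the list tests were chosen only after the result was seen. Among 6009 pairs of a named region and an alternative, 0 were reversed. The stricter threshold and the 1.5-fold minimum reuse the main folds, so pairs with these 2 alternatives could not reverse. Pairs in which a region not called in the main test changed sign were left out of this count. It therefore speaks only for regions called in the main test. Called regions, in the order subset in WT, subset in FntbKO, genotype in cTreg and genotype in eTreg, were 510, 136, 107 and 47 at an adjusted p of 0.01, by construction fewer. Leaving out each library gave 427 to 3664, 5 to 2249, 41 to 723 and 9 to 507, from fewer samples. Without WT cTreg 2 and FntbKO cTreg 1 they were 4225, 38, 43 and 698. With a replicate block across groups they were 4141, 2480, 990 and 655, and with pairs within genotype the subset counts were 5163 and 3342. The cause of these rises was not tested. Nor was the cause of the counts that rose above the main ones when libraries were left out. DESeq2 called 407 regions between genotypes in eTreg cells, and fits of the compared groups alone called 247 in cTreg and 802 in eTreg cells, where the cause was not tested. Halved counts gave 1758 for the subset in FntbKO and 450 for genotype in eTreg cells, and the cause was not tested. Without clustered regions 301 calls in cTreg (107 higher, 194 lower) and 221 in eTreg cells were left, by construction. The interaction stayed at 0 without each library, from 0 to 0. Regions shared by the genotype comparisons numbered 218 with the replicate block and 7 to 94 without each library. The FntbKO median at WT-higher regions ranged from 0.697 to 1.37 without each library, and that at WT-lower regions from -0.663 to -0.43, with -0.474 under pairs within genotype.

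Lists called, in the same order, were 3, 4, 6 and 3, and 0 for the interaction. With an estimated correlation they were 0, 0, 0 and 0. With 1 value per gene they were 2 in the cTreg and 1 in the eTreg genotype comparison, from fewer values. Without WT cTreg 2 and FntbKO cTreg 1 they were 5 for the subset in WT, 1 for genotype in cTreg cells and 1 for the interaction, and the cause was not tested. Leaving out each library gave 2 to 5, 3 to 4, 1 to 6, 1 to 3 and 0 to 1. Counts stayed within 1.5-fold under the other scalings, filters, the 1.5-fold minimum and without the X chromosome. Motif enrichment and the corrections for GC content and width, alone or with blocks, were not run, and blocks by pairs within genotype apply only to the subset comparisons and the interaction. Where an omission left a group with 1 library, that library is assumed to vary like the other groups. With this depth and number of libraries, in simulated data 10% to 26% of 1.5-fold changes were recovered in the 4 comparisons and 2% in the interaction.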

Other observations

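No tests were added for this part, and its windows of 1 Mb were chosen only after the result was seen.

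Regions called between the genotypes in cTreg cells gathered at loci beyond Slc39a11 and the Trim genes. On chromosome 4, between 63480679 and 63939976, 4 regions beside Tnfsf8, Tnc, Whrn and a neighbour were called higher in FntbKO cTreg cells, and 4 of this stretch were called higher in eTreg cells. Tnfsf8 encodes the ligand of the receptor CD30. On chromosome 17, between 35231019 and 35764358, within the major histocompatibility complex, 6 regions beside Nfkbil1, Ddr1 and Ier3 were called, 1 higher and 5 lower, of 107 tested in the window. On chromosome 5, between 105345195 and 105840540, 5 regions were called beside Gbp6 and genes of the Lrrc8 family of volume-regulated anion channels, 2 higher and 3 lower. On chromosome 7, between 82110019 and 82911744, 7 regions beside Sh3gl3 and Mex3b were called, 1 higher and 6 lower, of 36 tested in the window. Chromosome 11, which also holds the Slc39a11 interval, had 5 called regions between 109193236 and 109860959, all lower, of 83 tested in the window. Arsg, Fam20a and Rgs9 were among their genes. On chromosome 2, between 60328416 and 60809999, 4 regions beside Ly75, Pla2r1 and Rbms1 were called, 3 higher and 1 lower. No explanation of these stretches was tested separately.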
